A study of Mus musculus with 77 samples.

How the data were processed

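The series holds RNA sequencing of polyadenylated RNA from 77 mouse libraries in 27 groups, in 3 experiments of 33 (TetO), 18 (lentiviral) and 26 (MyoD) libraries. Groups were taken from the titles and characteristics of the samples. Per the labels, the lentiviral libraries were prepared at another centre and with a stranded kit, while the TetO and MyoD libraries were non-directional. Library preparation therefore goes with the experiment, and no test was made across experiments.

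Per the submitters' processing notes, kallisto and edgeR were used and the genome build was GRCm38.p6. Versions, parameters and the transcript annotation are not given in the sources used here. Each of the deposited files is a kallisto table with 1 line per transcript. Per the file headers, the authors deposited estimated counts, which kallisto assigns to each transcript and which are neither normalised nor rounded. The deposited TPM values in the same files are scaled by the authors' kallisto run to transcript length and library size. The effective length per transcript, as deposited, is in bases. The estimated counts were used for every test, and the TPM and effective lengths only for the length offsets named below.

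Transcripts were assigned to genes with the GENCODE M21 annotation of GRCm38 by their identifiers without version, and estimated counts were summed per gene and rounded to whole numbers. Of 106332 transcripts per file in the TetO and MyoD experiments 684 had no match, and of 106254 in the lentiviral experiment 894. These held between 0.17 and 0.704 percent of the counts of a library and were left out. Myf6 counts hold both the endogenous gene and the transgene, so Myf6 stayed out of every gene list.

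Each experiment was fitted on its own with edgeR 4.0.16 in R 4.3.3, with all its groups in 1 model without an intercept. Genes passed filterByExpr with the groups (16588 genes in the TetO, 16047 in the lentiviral and 16775 in the MyoD experiment). Library sizes were scaled by TMM, dispersions estimated with estimateDisp, and groups compared with the quasi-likelihood F test (glmQLFit and glmQLFTest). P-values were adjusted within each comparison by the method of Benjamini and Hochberg, and genes with an adjusted p below 0.05 were called. The standard error is the log2 fold change divided by the root of the F statistic. There were 23 comparisons, 9 in the TetO, 5 in the lentiviral and 9 in the MyoD experiment, of which 2 were interactions of genotype and day. A fold against a group with no counts was computed against a floor of 3 counts over the group and is a lower bound.

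Gene lists were written before the data were examined, as were the comparisons, the alternatives not named below as added, and the rule for naming genes. The 21 lists are muscle stem and progenitor, myogenic differentiation and fusion, embryonic and slow sarcomere, fast and mature sarcomere, fibroblast, TGF-beta response, Wnt/beta-catenin response, cAMP/CREB response, Notch pathway, cell cycle, interferon response, p53 targets, mitochondrially encoded, adipocyte, cartilage and bone, smooth muscle, cardiomyocyte, endothelial, macrophage and blood, neural and Schwann, and epithelial genes. For each list the called members were counted, once with p-values adjusted over all genes and once over the list alone. Lists were also tested as sets with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 21 lists of a comparison.

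Genes were named by a rule. It allows a panel of 12 genes (Myf6, Myod1, Myf5, Myog, Pax7, Mymk, Mymx, Myh3, Acta1, Ckm, Thy1 and Col1a1). It adds the 5 largest rises and the 5 largest falls among called genes with a mean of at least 10 CPM in the higher group, every library of the higher group above every library of the lower, and a symbol that is not a clone name. Of each list it allows up to 3 called members with the largest change in the direction most called members took and 1 in the other, or, where none was called, the member with the highest level. For the interactions the condition on every library was dropped. Genes outside the rule are marked as chosen after their values were seen.

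The tests were tested on simulated data with the levels and dispersions of 4 comparisons, in each of which 50 genes were changed by each of 1.5-, 2-, 4- and 8-fold. In the TetO comparison of Myf6 with medium on day 2, 20, 68, 80 and 98 percent of these were called in the right direction. In the lentiviral day 2 comparison with MEFs the shares were 4, 30, 78 and 94 percent, in the comparison of MyoD genotypes on day 0 18, 58, 80 and 94 percent, and on day 6, with 2 libraries per group, 10, 32, 74 and 84 percent. False calls numbered 3, 2, 5 and 3.

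The labels do not say whether a replicate number links groups, which was checked by correlating the deviations of same-numbered libraries from their group means. A number was taken to pair libraries where all 3 correlations exceeded 0.1, as in 10 of 23 comparisons (TetO 6, lentiviral 4, MyoD 0). The cut can miss links: clones aside, Y-linked Ddx3y went with the number within the TetO, lentiviral, knockout and wild-type libraries. No first-choice fit used a block. TetO file names swap replicates 1 and 3 against the titles, whose numbers are used here.

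Alternatives were RLE size factors, the DESeq2 1.42.0 Wald test with its own size factors, no filter except for genes without counts, a fit of only the groups compared, replicate number as a block, average transcript length as an offset, and leaving out each library in turn. Camera was repeated with the correlation estimated from the data and with the replicate block. Added after the data were seen were a block for replicate number within each MyoD genotype and a fit without both F/R/C libraries numbered 1 of days 6 and 12 of the TetO experiment. Also added was the averaged genotype effect of the MyoD experiment with days 0, 2 and 12 alone, as they are and summed by replicate number. Other splits of the same libraries were counted for comparisons with at least 3 libraries per group, with all 10 splits of 6 libraries, or 100 random ones for the interactions, in fits of only the groups compared.

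The MyoD comparison on day 6 and that of the clones have 2 libraries per group, and a fit without 1 of these assumes that the remaining library varies like the other groups. Coordinates are those of GRCm38, counted from 1 with both ends included.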

Results

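Polyadenylated RNA was sequenced from 77 mouse libraries in 27 groups, which followed embryonic fibroblasts (MEFs) as the muscle regulator Myf6 was switched on with doxycycline at 2 µg/mL. The target state was the induced myogenic progenitor cell, shortened here to iMPC. The TetO experiment held 33 libraries in 11 groups of 3. Its MEFs were positive for the surface antigen Thy1 and carried a doxycycline-inducible Myf6 transgene. They were sampled on day 0, on days 2, 6 and 12 in iMPC medium, with Myf6 or with Myf6 and F/R/C, and as picked clones. F/R/C stands for forskolin at 5 µM, which activates adenylyl cyclase, RepSox at 5 µM, which inhibits the TGF-beta type I receptor, and CHIR99021 at 3 µM, which inhibits GSK3. The lentiviral experiment held 18 libraries in 6 groups of 3, from Thy1-positive MEFs that received inducible Myf6 by lentivirus. The MyoD experiment held 26 libraries in 10 groups, from MEFs lacking MyoD and from wild-type MEFs given lentiviral Myf6 and F/R/C. Its groups had 3 libraries on days 0, 2 and 12 and 2 libraries on day 6 and for the clones. Clones were kept in F/R/C without doxycycline. Library depth in M estimated counts (M, 1e+06) was 17.7 to 31.9 (TetO), 20.7 to 37.6 (lentiviral) and 19.2 to 33.5 (MyoD). Levels are CPM (counts per M counts, TMM-scaled) as mean ± SD, n = 3 unless stated. Changes are log2 fold changes with standard error (SE) and adjusted p from edgeR. The labels do not say that libraries of a group are independent cultures. By Y-linked Ddx3y every group except MyoD wild-type clones held both sexes. The p-values use the spread over all groups of an experiment.

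**Figure D1:**
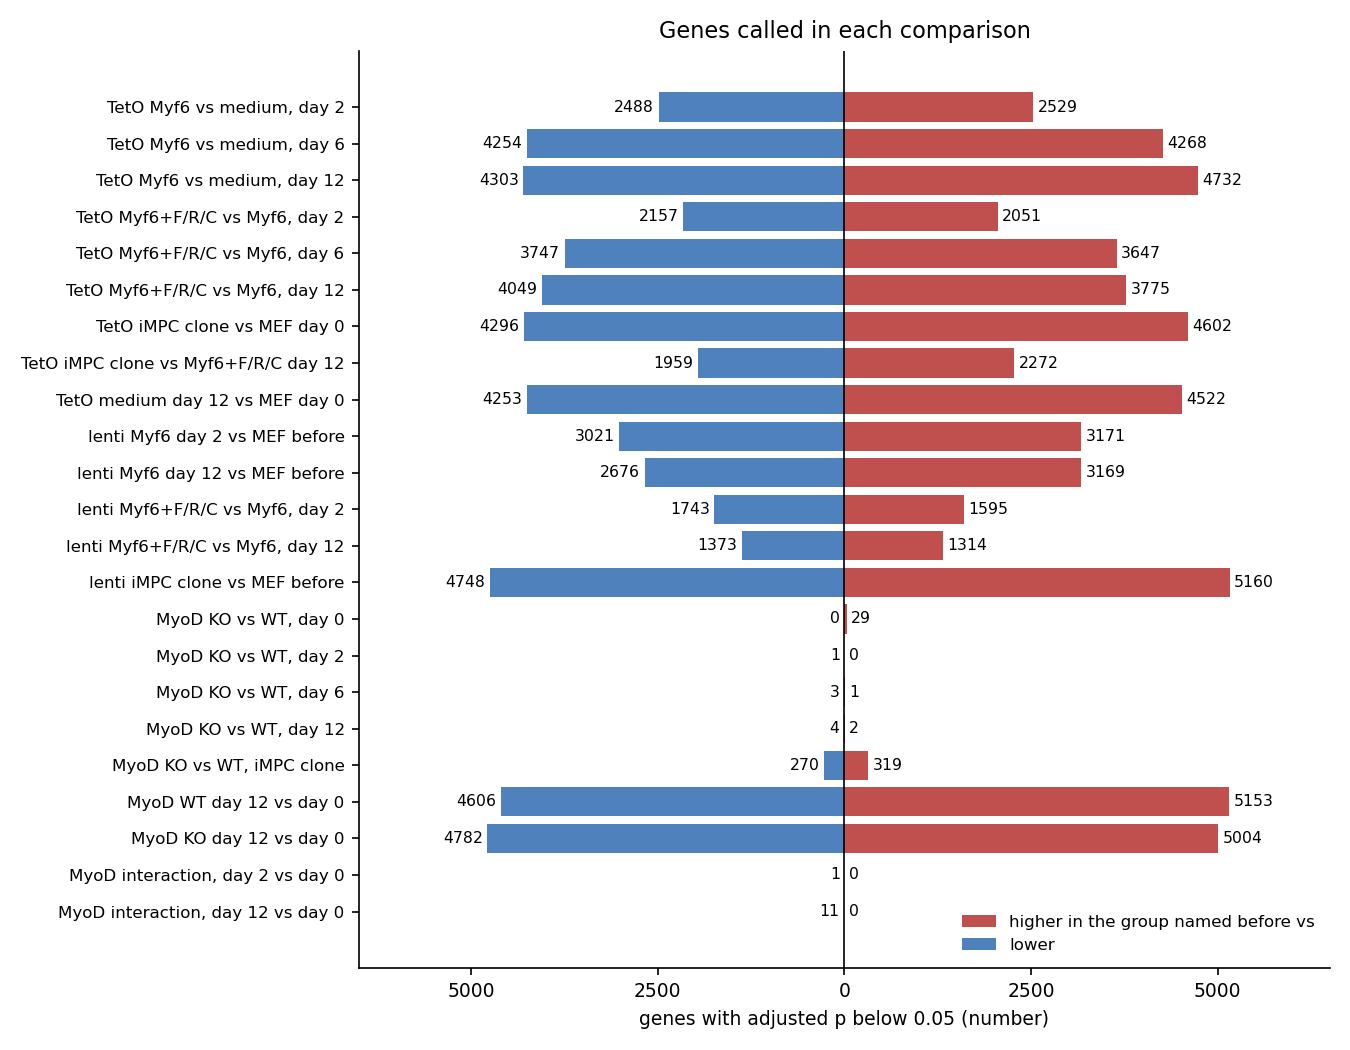
The bars give the number of genes with an adjusted p below 0.05 in each comparison, those higher in the group named before vs to the right and those lower to the left. The MyoD knockout and wild type differed by 29 genes on day 0, while the clones of the lentiviral experiment differed from their MEFs by 5160 higher and 4748 lower genes.

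The targeted genes were measured ahead of the comparisons. Myf6 (ENSMUSG00000035923.4, GRCm38 chromosome 10, 107492853 to 107494737) was counted together with its transgene. It lay between 6.49 and 7.35 CPM in TetO MEFs on day 0, between 1053 and 1346 CPM in the Myf6 groups and between 226.5 and 956 CPM with F/R/C. Lentiviral cultures held between 19.7 and 35.0 CPM of Myf6 before induction and on day 2 between 4378 and 7009 CPM with Myf6 and between 770.2 and 2242 CPM with F/R/C as well. The clones of the TetO and lentiviral experiments, which were off doxycycline, held 53.9 ± 24.1 and 67.2 ± 42.95 CPM of Myf6. In the MyoD experiment, Myod1 (ENSMUSG00000009471.4, chromosome 7, 46376474 to 46379099) was not absent from the knockout counts: knockout MEFs on day 0 held 10.7 to 12.6 CPM and wild-type MEFs 0.139 to 0.659 CPM. Knockout libraries then held 5.02 to 7.60 CPM of Myod1 on day 2, 14.7 to 19.9 CPM on day 6, 14.5 to 30.8 CPM on day 12 and 53.6 to 90.8 CPM in the clones. Wild-type libraries held 0.190 to 1.77, 169 to 178, 68.2 to 227 and 287 to 374 CPM at the same times. An allele that keeps part of the transcript leaves such counts, so the level is no test of the genotype label.

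**Figure D2:**
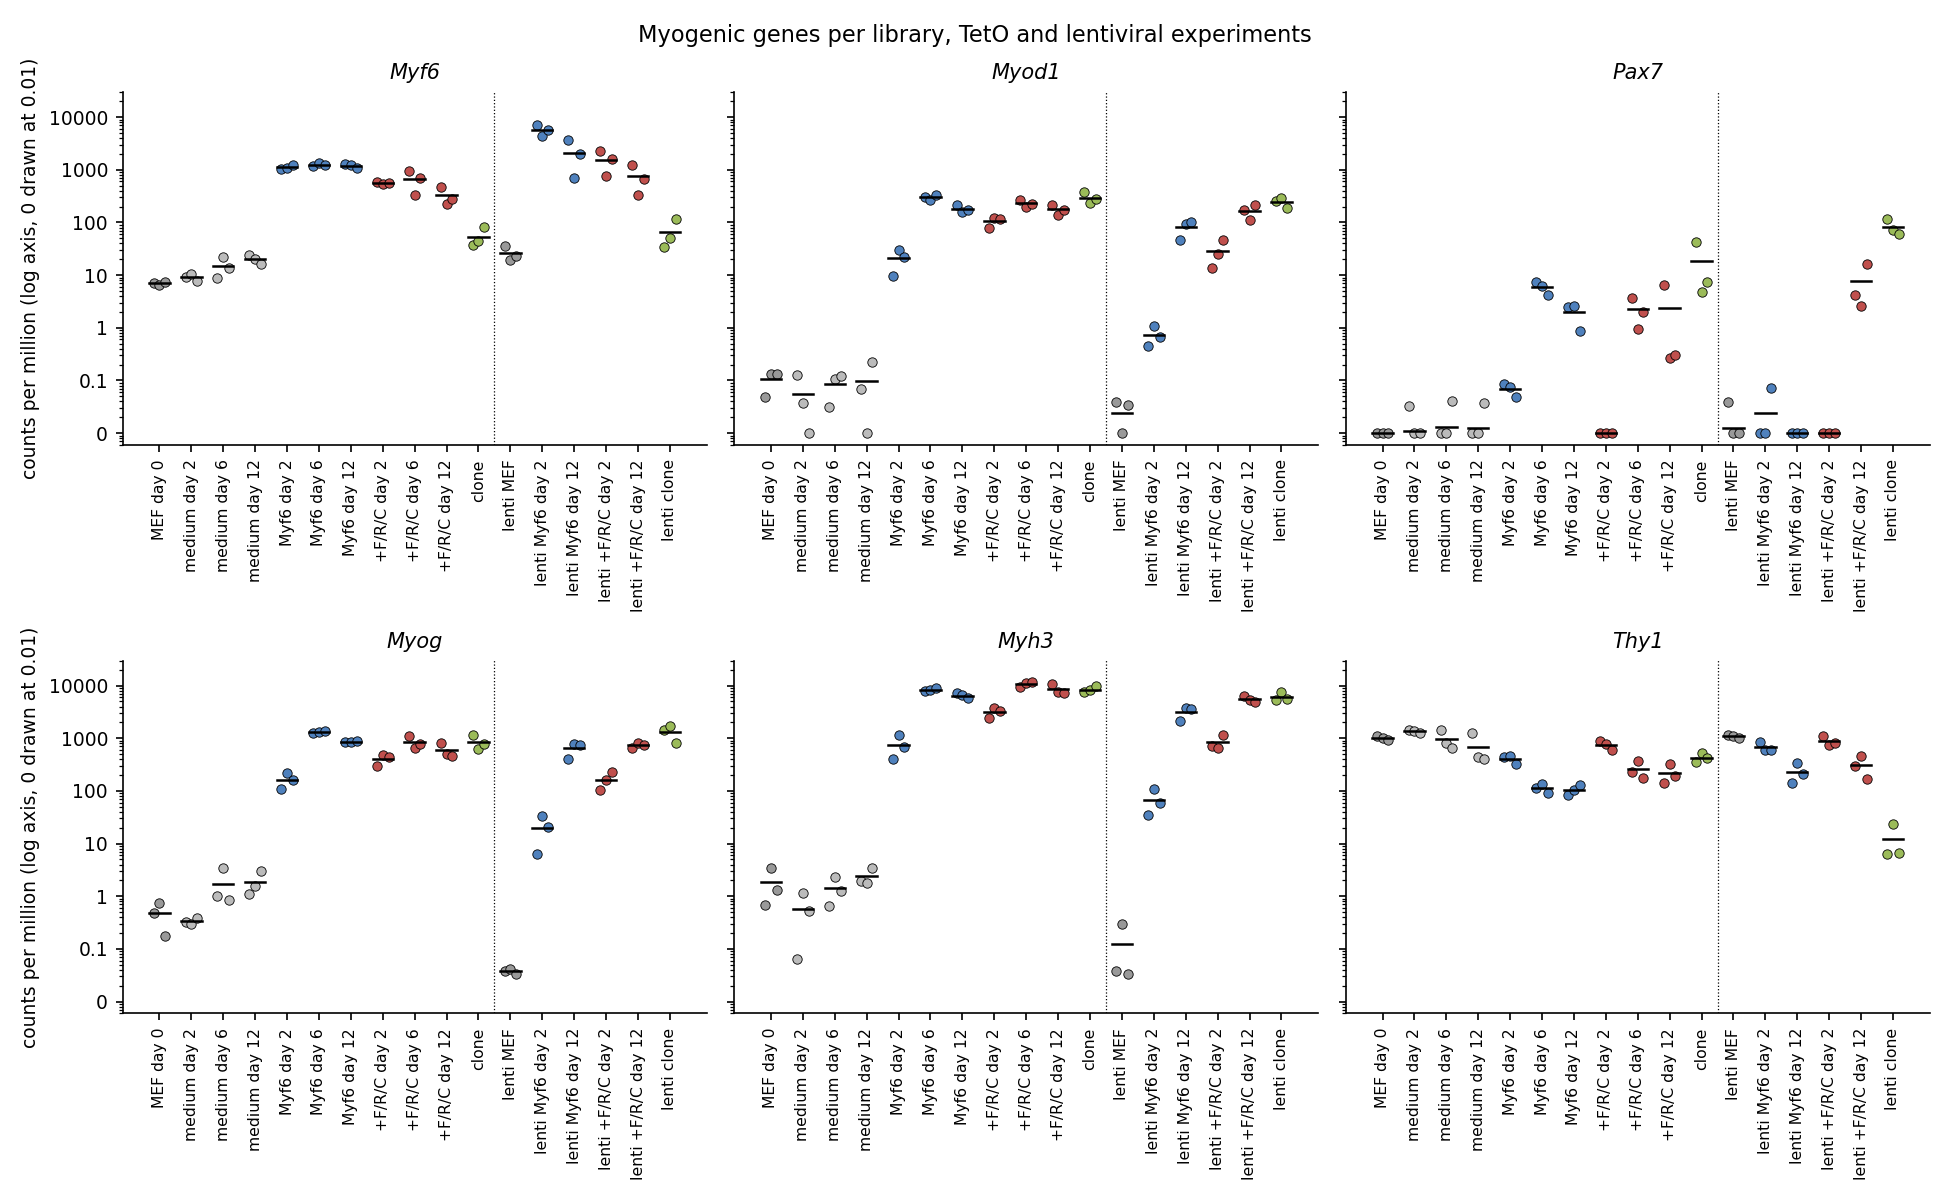
Each point is a library and each line a group mean, in CPM on a log axis, for Myf6, Myod1, Pax7, Myog, Myh3 and Thy1 in the TetO (left of the dotted line) and lentiviral groups. Myh3 lay at 1.83 ± 1.45 CPM in TetO MEFs on day 0 and at 8435 ± 1113 CPM in the TetO clones.

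TetO cultures with Myf6 were set against medium, which held no doxycycline, so the drug is part of these comparisons. By day 2 Myog, the regulator of terminal muscle differentiation, rose from 0.340 ± 0.0488 to 161 ± 54.5 CPM (log2 fold change 8.87, SE 0.53, adjusted p = 5.02e-13) and Myod1 from 0.0555 ± 0.0663 to 20.9 ± 10.5 CPM (8.40, SE 0.55, adjusted p = 2.41e-12). The fusion gene Mymk rose by 9.86 (SE 0.48), the embryonic acetylcholine receptor subunit Chrng by 13.25 (SE 0.38) and the embryonic myosin Myh3 by 10.36 (SE 0.63). All 17 differentiation and fusion genes, all 15 embryonic and slow sarcomere genes and all 28 fast and mature sarcomere genes were higher, with the same counts adjusted over the list alone. Of 19 measured stem and progenitor genes, 12 were higher and 2 lower, again the same adjusted over the list alone, but Pax7, the satellite cell regulator, lay at 0.0689 ± 0.0189 CPM and Myf5 at 0. In the Notch pathway 7 of 12 genes were higher (7 adjusted over the list alone), among them Heyl (7.41, SE 0.81) and the ligand Dll1 (5.45, SE 0.33). Of 29 fibroblast genes, 17 were lower and 1 higher (17 and 2 adjusted over the list alone). Pdgfra fell from 512 ± 143 to 21.2 ± 2.64 CPM, Thy1 from 1376 ± 104 to 409 ± 77.3 CPM and Col1a1 from 7937 ± 1051 to 3568 ± 761 CPM (adjusted p = 1.69e-07, 0.000512 and 0.00673). Of 26 cell cycle genes 22 were lower (25 adjusted over the list alone), with Mki67 at 52.7 ± 3.07 against 149 ± 20.4 CPM. Of 16 interferon response genes 15 were lower (16 adjusted over the list alone), with Ifit3 at 0.977 ± 0.775 against 60.1 ± 44.1 CPM. Of the other cell types 2 of 4 epithelial genes were higher, 4 of 11 neural and Schwann genes higher and 2 lower (the same adjusted over the lists alone), and 3 of 8 smooth muscle genes higher and 1 lower (4 and 2 adjusted over the list alone). Of 13 mitochondrially encoded genes 5 were higher (11 adjusted over the list alone). In all 5017 genes were called, 2529 higher and 2488 lower, and 2760 of them changed at least 2-fold. With only the groups compared in the fit 7834 were called.

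By day 6 Myod1 reached 299.5 ± 33.1 CPM against 0.0866 ± 0.0483 in medium (log2 fold change 11.73, SE 0.53), Myog 1329 ± 57.1 CPM against 1.75 ± 1.44 (9.57, SE 0.51) and Myh3 8397 ± 497 CPM against 1.41 ± 0.819 (12.55, SE 0.66). The fast myosin Myh4, with no counts in medium, reached 495 ± 91.4 CPM and was at least 14000-fold higher, against a floor of 3 counts over the group. Of the sarcomere lists 15 of 15 embryonic and slow and 28 of 28 fast and mature genes were higher, and 16 of 17 differentiation and fusion genes (the same counts adjusted over the list alone). Pax7 was called at a low level, 5.95 ± 1.56 against 0.0133 ± 0.0231 CPM (8.46, SE 1.48, adjusted p = 4.76e-05). Fibroblast genes were lower in 26 of 29 cases (27 adjusted over the list alone). Col1a1 fell from 22260 ± 9112 to 1382 ± 335 CPM, Pdgfra fell by 7.24 on the log2 scale and Dpt, a gene of dermal fibroblasts, from 233 ± 127 to 0.198 ± 0.0807 CPM. Mitochondrially encoded genes were higher in 12 of 13 cases (12 adjusted over the list alone), with mt-Nd2 at 2796 ± 262 against 938 ± 182 CPM. The cell cycle inhibitor Cdkn1a rose to 1487 ± 47.0 from 296 ± 101 CPM (2.33, SE 0.18), while of the 12 p53 targets 3 were higher and 3 lower (the same adjusted over the list alone). The comparison called 8522 genes, 4268 higher and 4254 lower.

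On day 12 the comparison with medium called 9035 genes, 4732 higher and 4303 lower. Muscle genes stayed high: Myh3 lay at 6492 ± 733 against 2.44 ± 0.926 CPM, Myog at 865 ± 13.1 against 1.89 ± 0.965 CPM and Myh4 at 869 ± 212 CPM against no counts, at least 23800-fold higher (floor of 3 counts over the group). Of the muscle lists, 16 of 17 differentiation and fusion genes, 15 of 15 embryonic and slow genes and 27 of 28 fast and mature genes were higher, the same adjusted over the list alone. The macrophage and blood list rose, with 11 of 12 genes higher (11 adjusted over the list alone; camera adjusted p = 3.86e-06, adjusted p = 0.0661 with an estimated correlation). The complement gene C1qb was at 127 ± 57.2 against 1.48 ± 0.832 CPM and the myeloid adaptor Tyrobp at 29.8 ± 12.8 against 0.382 ± 0.266 CPM. The summed list held 682 to 1610 CPM in the 3 Myf6 libraries and at most 66.4 CPM in any other TetO library. Adipocyte genes went the other way, with 7 of 9 lower (7 adjusted over the list alone). Fabp4, the fatty acid carrier of fat cells, was at 0.373 ± 0.240 with Myf6 and at 230.3 ± 217 CPM in medium. The adipokine Adipoq had no counts with Myf6 and 61.6 ± 57.6 CPM in medium. All 4 measured epithelial genes were higher (4 adjusted over the list alone), with Cldn4 at 5.94 ± 0.662 against 0.0112 ± 0.0195 CPM. Of 10 cartilage and bone genes 1 was higher and 5 lower (3 and 5 adjusted over the list alone), with Comp, a cartilage matrix protein, down from 188 ± 82.0 to 1.38 ± 0.372 CPM. Smooth muscle genes gave 3 higher and 2 lower of 8, cardiomyocyte genes 3 and 3 of 9, endothelial genes 3 and 2 of 8, and neural and Schwann genes 3 and 2 of 11, with the same counts adjusted over the list alone except for 4 lower neural and Schwann genes. Interferon response genes were lower in 14 of 16 cases and higher in 1 (14 and 1 adjusted over the list alone), with Isg15 at 1.54 ± 0.230 against 71.3 ± 57.4 CPM. The remaining lists moved both ways, with the TGF-beta response at 5 higher and 4 lower of 14, the Wnt/beta-catenin response at 7 and 4 of 12 and the cAMP/CREB response at 4 and 6 of 16, the same adjusted over the list alone.

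**Figure D3:**
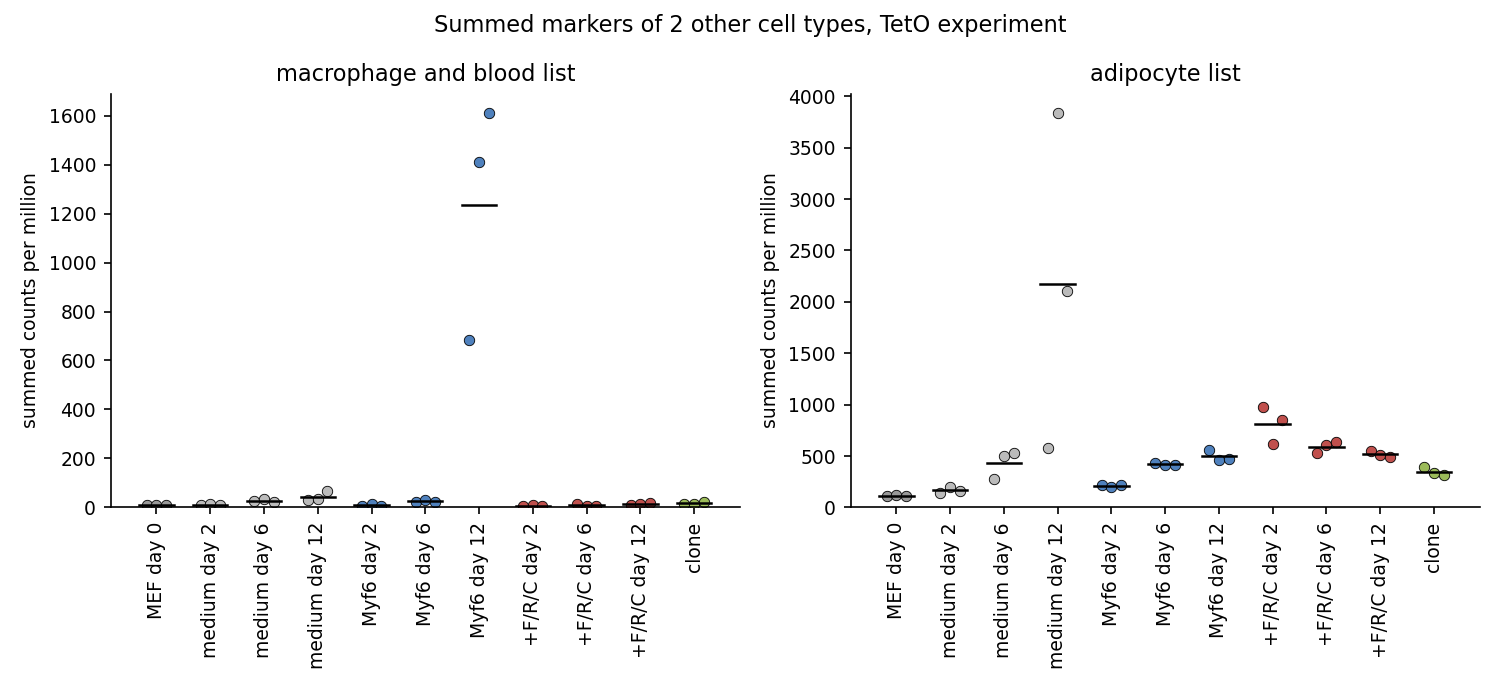
Each point is a TetO library and each line a group mean of the summed CPM of the fixed macrophage and blood list and the fixed adipocyte list. The macrophage and blood sum was 1230 ± 488 CPM in Myf6 on day 12 and 43.7 ± 19.8 CPM in medium on day 12, and the adipocyte sum was 2180 ± 1630 CPM in medium on day 12.

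Adding F/R/C to Myf6 tested the 3 compounds, with lower mean Myf6 as part of the comparison in both experiments. On day 2 Myod1 rose from 20.9 ± 10.5 to 105 ± 24.4 CPM (2.33, SE 0.31, adjusted p = 2.78e-06), Myog from 161 ± 54.5 to 406 ± 96.6 CPM (1.33, SE 0.35) and the fast myosin Myh1 from 36.4 ± 15.7 to 529.8 ± 132 CPM (3.87, SE 0.44). Of 28 fast and mature sarcomere genes 19 were higher and none lower (19 adjusted over the list alone; camera adjusted p = 2.82e-10, adjusted p = 0.125 with an estimated correlation), including the calcium pump Atp2a1 (3.13, SE 0.28) and the thin filament protein Neb (3.56, SE 0.28). In the compounds' pathways 10 of 14 TGF-beta response genes were lower and 1 higher (10 and 2 adjusted over the list alone). Ccn2 fell from 276.5 ± 37.3 to 25.7 ± 4.84 CPM and Pmepa1 from 178 ± 6.44 to 18.6 ± 0.794 CPM. By contrast 11 of 16 cAMP/CREB response genes were higher (11 adjusted over the list alone), with Gem at 35.5 ± 3.51 against 7.87 ± 2.32 CPM. Of 12 Wnt/beta-catenin response genes 5 were higher and 2 lower (5 and 3 adjusted over the list alone). Cell cycle genes were higher in 20 of 26 cases (23 adjusted over the list alone), among them Aurkb (1.31, SE 0.34). Fibroblast genes split, 10 higher and 10 lower (11 and 11 adjusted over the list alone): Lum rose from 1.90 ± 0.0970 to 161 ± 53.2 CPM and Fn1, the matrix fibronectin, fell from 7903 ± 1507 to 742 ± 135 CPM. Magel2, an imprinted gene, had the largest rise under the naming rule's limits (6.98, SE 0.44). Of 4 epithelial genes 3 were lower (3 adjusted over the list alone), with Krt8 at 0.649 ± 0.328 against 36.4 ± 2.50 CPM. Of 9 adipocyte genes 4 were higher, of 8 endothelial genes 3, of 13 mitochondrially encoded genes 3, and of 8 smooth muscle genes 1 was higher and 3 lower (the same adjusted over the lists alone). Myf6 itself was lower with F/R/C at 563 ± 19 against 1121 ± 97.2 CPM (-0.99, adjusted p = 0.0215). That call was lost without Myf6 replicate 3 (adjusted p = 0.0785) and without F/R/C replicate 1, 2 or 3 (0.0542, 0.071 and 0.0589). In all 4208 genes were called, 2051 higher and 2157 lower, and 7596 with only the groups compared in the fit.

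On day 6 F/R/C raised part of the mature sarcomere list. Myod1 was at 229.5 ± 36.0 with and 299.5 ± 33.1 CPM without F/R/C (-0.38, adjusted p = 0.292) and Myog at 844 ± 214 and 1329 ± 57.1 CPM (-0.66, adjusted p = 0.126). The fast and mature list had 15 of 28 genes higher and 1 lower (18 and 2 adjusted over the list alone), among them Myoz1, a Z-disc protein, at 259 ± 25.2 against 3.34 ± 0.561 CPM and Casq1, the fast-fibre calcium store, at 777 ± 40.3 against 45.1 ± 13.4 CPM. The acetylcholine receptor subunit Chrnb1 fell from 326 ± 22.1 to 78.2 ± 13.2 CPM. Of 16 cAMP/CREB response genes 12 were higher (13 adjusted over the list alone), led by Nr4a1 (3.12, SE 0.28). The Wnt/beta-catenin response genes gave 3 higher and 3 lower of 12 (the same adjusted over the list alone). Axin2, a direct target, rose from 8.73 ± 0.947 to 25.8 ± 3.85 CPM and the secreted inhibitor Wif1 fell from 27.8 ± 2.16 to 0.482 ± 0.472 CPM. The TGF-beta target Pmepa1 fell by 2.40 on the log2 scale, and Gdf6, a secreted growth factor, from 159 ± 29.7 to 0.846 ± 0.734 CPM. Lingo3 rose from 0.0869 ± 0.0776 to 35.4 ± 8.15 CPM. Macrophage and blood genes were lower in 9 of 12 cases and higher in 1 (the same adjusted over the list alone), with C1qa at no counts against 2.65 ± 0.763 CPM, at least 63.4-fold lower (floor of 3 counts over the group). Myf5, a regulator of early myoblasts, was called at 1.14 ± 0.987 against 0.0288 ± 0.0499 CPM (5.01, adjusted p = 0.0144). Without Myf6 replicate 3 its adjusted p was 0.0591, and with DESeq2 it was 0.115, the highest of 6 alternatives, whose lowest was 0.000924. Myf6 was at 662 ± 315 against 1257 ± 82.6 CPM (-0.93, adjusted p = 0.0194), a call lost without Myf6 replicate 2 (0.0605) and without F/R/C replicate 2 (0.131). It was also lost in a fit of only the groups compared (0.16, the highest of its alternatives, whose lowest was 0.00166). The comparison called 7394 genes, 3647 higher and 3747 lower, and 2851 with only the groups compared in the fit. F/R/C replicate 1 of day 6 stood apart from its group, with a mean correlation of 0.881 against 0.931 and 0.934 for the other libraries. Without it and replicate 1 of day 12 Pax7 was called lower (-1.99, adjusted p = 0.0281, against -1.42 and 0.211 with all libraries).

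On day 12 cultures with F/R/C lacked the macrophage transcripts of cultures with Myf6 alone. All 12 macrophage and blood genes were lower (12 adjusted over the list alone; camera adjusted p = 1.43e-10, adjusted p = 0.0206 with an estimated correlation), with C1qa, Adgre1 and Msr1 at no counts, at least 3170-fold, 1490-fold and 697-fold below Myf6 alone (floor of 3 counts over the group). Of the muscle regulators, Myod1 and Myog did not pass: Myod1 lay at 177 ± 39.1 against 183 ± 28.4 CPM (adjusted p = 0.902) and Myog at 588 ± 187 against 865 ± 13.1 CPM (adjusted p = 0.191). The fast and mature list had 11 of 28 genes higher and 4 lower (12 and 4 adjusted over the list alone). Ckm, the muscle creatine kinase, rose by 1.89 (SE 0.32), Myoz1 by 6.24 (SE 0.42) and Mybpc2 by 6.48 (SE 0.47), while the type IIa myosin Myh2 fell from 152 ± 21.01 to 45.1 ± 20.2 CPM. Myf5 was higher at 3.35 ± 2.53 against 0.0545 ± 0.0944 CPM (5.61, SE 1.37, adjusted p = 0.00296), a call that ended with DESeq2 at 0.0578, the highest of its alternatives, whose lowest was 0.000779. Pax7 lay at 2.38 ± 3.62 against 1.96 ± 0.935 CPM (0.24, adjusted p = 0.857), and this rested on F/R/C replicate 1: without it the change was -2.76 (adjusted p = 0.0165). Among pathway genes, 6 of 16 cAMP/CREB response genes were higher (6 adjusted over the list alone), with Nr4a1 at 167 ± 10.0 against 24.7 ± 1.51 CPM and Pde4b up by 3.00 (SE 0.29). Of 14 TGF-beta response genes 7 were lower and 2 higher (the same adjusted over the list alone), with Ccn2 at 77.4 ± 17.5 against 636 ± 122 CPM. Fibroblast genes again split, 10 higher and 8 lower of 29 (10 and 9 adjusted over the list alone): Lum rose by 7.47 (SE 0.86) and Pdgfra from 6.02 ± 0.992 to 130.4 ± 78.8 CPM, and Fn1 fell from 9259 ± 509.5 to 651 ± 278 CPM. Myf6 fell from 1195 ± 96.2 to 325 ± 131 CPM (-1.88, adjusted p = 3.33e-05). In all 7824 genes were called, 3775 higher and 4049 lower.

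The TetO clones were set against day 0 MEFs to describe the established iMPC state, kept without doxycycline. Pax7 (ENSMUSG00000028736.13, chromosome 4, 139737062 to 139833528) lay at 18.4 ± 21.3 CPM and Myf5 (ENSMUSG00000000435.1, chromosome 10, 107482908 to 107486134) at 8.26 ± 6.72 CPM, both with no counts in MEFs. Clone replicate 1 held 42.92 and 15.92 CPM of them, the others 4.72 and 7.54 CPM of Pax7 and 3.41 and 5.43 CPM of Myf5. Myod1 reached 296 ± 71.7 against 0.105 ± 0.0485 CPM, Myog 853 ± 272 against 0.474 ± 0.289 CPM and Myh3 8435 ± 1113 against 1.83 ± 1.45 CPM. All 60 genes of the 3 differentiation and sarcomere lists were higher, and of 19 stem and progenitor genes 14 were higher and 3 lower, with the same counts adjusted over the lists alone. The acetylcholine receptor subunit Chrnd was at least 5820-fold higher than in MEFs, where it had no counts (floor of 3 counts over the group). Fibroblast genes were lower in 15 of 29 cases and higher in 5 (the same adjusted over the list alone), and Thy1 was still at 428 ± 82.9 against 1010 ± 75.6 CPM (-1.24, adjusted p = 0.00519). All 26 cell cycle genes were lower (26 adjusted over the list alone), and 11 of 14 TGF-beta response genes were lower and 2 higher (11 and 2 adjusted over the list alone). Col1a1 was called lower (2368 ± 321 against 3996 ± 340 CPM, adjusted p = 0.0472) only at the edge of the threshold: the call was lost in 4 of 6 alternatives, whose adjusted p reached 0.0619, without any of the 6 libraries compared (0.0535 to 0.129) and without 11 of the 27 other libraries (up to 0.0546). The comparison called 8898 genes, 4602 higher and 4296 lower.

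Set against F/R/C cultures of day 12, the TetO clones showed which genes differ once cells are picked and expanded without doxycycline. Myf6 was lower in the clones, at 53.9 ± 24.1 against 325 ± 131 CPM (-2.59, SE 0.33, adjusted p = 4.25e-06). Myh3 lay at 8435 ± 1113 against 8487 ± 2014 CPM (adjusted p = 0.994), while Myh7 was lower at 310 ± 86.55 against 823.5 ± 301 CPM (-1.41, adjusted p = 0.00288, with alternatives from 0.000991 to 0.0507). Of 28 fast and mature genes none was higher and 4 were lower (0 and 1 adjusted over the list alone). Pax7 was called higher (2.99, adjusted p = 0.0227), but its adjusted p was 0.321 without clone replicate 1, 0.0905 without F/R/C replicate 2 and 0.0966 without replicate 3, and among the alternatives it ran from 3.88e-05 to 0.125. Cell cycle genes were higher in 10 of 26 cases (12 adjusted over the list alone), with Tyms, the thymidylate synthase, at 16.7 ± 8.98 against 2.55 ± 1.12 CPM. Of 29 fibroblast genes 10 were higher (14 adjusted over the list alone). The chemokine Ccl2 rose by 5.42 (SE 0.74). The comparison called 4231 genes, 2272 higher and 1959 lower, and 6731 without F/R/C replicate 1 of day 6, which was not among the groups compared.

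Medium alone was followed from day 0 to day 12 to show what the cultures do without induced Myf6. The elastic fibre gene Eln went from 0.551 ± 0.136 to 1730 ± 969 CPM (11.61, SE 1.23), Col3a1 from 796 ± 44.8 to 18640 ± 4811 CPM (4.55, SE 0.33) and Adipoq from 0.0920 ± 0.0890 to 61.6 ± 57.6 CPM (9.31, SE 1.44). Of 29 fibroblast genes 21 were higher and 3 lower, all 9 adipocyte genes were higher and all 26 cell cycle genes were lower, the same adjusted over the lists alone. Top2a, a topoisomerase of dividing cells, fell from 353 ± 68.0 to 37.6 ± 9.43 CPM and Serpinb2 from 93.6 ± 10.0 to 0.355 ± 0.247 CPM. The immediate early gene Fos rose from 5.30 ± 0.865 to 297 ± 61.7 CPM. Macrophage and blood genes were higher in 7 of 12 cases (9 adjusted over the list alone), at a summed level of 29.5 to 66.4 CPM on day 12. Myf6 rose from 6.98 ± 0.446 to 20.1 ± 4.02 CPM without doxycycline (1.53, adjusted p = 0.000462). Thy1 lay at 698 ± 476 against 1010 ± 75.6 CPM (-0.53, adjusted p = 0.216) and was called lower without medium replicate 1 of day 12 (0.00379). The comparison called 8775 genes, 4522 higher and 4253 lower. This balance depends on the scaling: RLE size factors gave 5084 and 3751 and DESeq2 5488 and 3905, with the median of all genes moved by 0.11 log2 units.

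In the lentiviral experiment the first comparison asked what transduced Myf6 does by day 2 relative to MEFs sampled 1 day before induction. There was no medium control of the same day, so time in culture, transduction and doxycycline are part of this comparison. Myog rose from 0.0380 ± 0.00416 to 20.0 ± 13.3 CPM (8.90, SE 0.82, adjusted p = 3.03e-06), Myh3 from 0.122 ± 0.149 to 67.2 ± 38.1 CPM and Cdh15, a myoblast cadherin, from 0.228 ± 0.135 to 239.5 ± 89.4 CPM. Of 17 differentiation and fusion genes 14 were higher, of 15 embryonic and slow genes 14, and of 28 fast and mature genes 19 higher and 1 lower, with the same counts adjusted over the lists alone. All 16 interferon response genes were higher (16 adjusted over the list alone; camera adjusted p = 5.73e-10, adjusted p = 0.064 with an estimated correlation), with Isg15 at 30.3 ± 16.0 against 1.16 ± 0.354 CPM, Usp18 at 37.6 ± 12.0 against 1.33 ± 0.346 CPM and Rsad2 at 9.47 ± 1.72 against 0.217 ± 0.134 CPM. Of 12 p53 targets 7 were lower (7 adjusted over the list alone), with Mdm2 at 157 ± 12.3 against 381 ± 30.9 CPM, and Nr4a1 fell by 3.66 on the log2 scale (SE 0.30). Fibroblast genes were lower in 7 of 29 cases (6 lower adjusted over the list alone), while Thy1 (-0.67, adjusted p = 0.264) and Col1a1 (-1.33, adjusted p = 0.173) passed only in a fit of the groups compared (0.0126 and 0.000345, the lowest of their alternatives, which reached 0.294 and 0.196). The comparison called 6192 genes, 3171 higher and 3021 lower.

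By day 12 of lentiviral Myf6 Myod1 rose from 0.0240 ± 0.0209 to 80.9 ± 30.0 CPM (11.43, SE 0.76), Myog to 644 ± 202 CPM (13.90, SE 0.85), Mymk to 250.4 ± 82.9 CPM (13.86, SE 0.84) and Myh3 from 0.122 ± 0.149 to 3141 ± 870 CPM. Myh4 lay at 190.2 ± 151 CPM against no counts, and the fast troponin Tnnc2 at 426.5 ± 169 against 0.0280 ± 0.0486 CPM. All 28 fast and mature and all 15 embryonic and slow genes were higher, with 15 of 17 differentiation and fusion genes (the same adjusted over the lists alone). Pax7 had no counts in Myf6 cultures of day 12. Interferon response genes were still higher in 14 of 16 cases (14 adjusted over the list alone), with Usp18 at 13.1 ± 2.16 CPM against 1.33 ± 0.346 before and Rsad2 at 3.56 ± 2.07 against 0.217 ± 0.134 CPM. The p53 target Pmaip1 fell from 220.2 ± 13.3 to 69.0 ± 16.2 CPM, 1 of 7 lower p53 targets of 12 (7 adjusted over the list alone), and the matrix gene Tnc fell by 2.72 on the log2 scale. Cd36, a fatty acid transporter of adipocytes and muscle, rose from 1.07 ± 0.672 to 81.2 ± 47.7 CPM. Thy1 fell from 1090 ± 88.5 to 228 ± 101 CPM (adjusted p = 0.00205). Col1a1 was at 2456 ± 1766 against 8143 ± 1477 CPM (adjusted p = 0.0873) and was called with a replicate block (0.0253), with DESeq2 (0.044) and without clone replicate 1 (0.0444), while its other alternatives reached 0.104. The comparison called 5845 genes, 3169 higher and 2676 lower.

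With F/R/C beside lentiviral Myf6, Myod1 rose on day 2 from 0.731 ± 0.314 to 28.5 ± 16.7 CPM (5.24, SE 0.50, adjusted p = 5.43e-05), Myog from 20.0 ± 13.3 to 164 ± 63.0 CPM (3.03, SE 0.48) and the perinatal myosin Myh8 from 2.25 ± 1.92 to 118 ± 36.0 CPM (5.68, SE 0.61). Of 28 fast and mature genes 22 were higher and of 15 embryonic and slow genes 13, and none of either list was lower (24 higher and 1 lower, and 13 higher, adjusted over the lists alone). Mstn, a secreted inhibitor of muscle growth, rose from 0.0794 ± 0.0517 to 14.5 ± 5.89 CPM. Interferon response genes were lower in 15 of 16 cases (16 adjusted over the list alone; camera adjusted p = 9.19e-15, adjusted p = 0.0209 with an estimated correlation), with Isg15 at 1.33 ± 0.597 against 30.3 ± 16.0 CPM. The TGF-beta target Pmepa1 fell by 2.55 on the log2 scale (SE 0.36). Myf6 lay at 1546 ± 739 against 5698 ± 1315 CPM (-1.88, adjusted p = 0.042), a call lost without Myf6 replicate 1 or 3 (0.138 and 0.0866) and without F/R/C replicate 2 or 3 (0.158 and 0.108), and without any MEF library, Myf6 replicate 3 of day 12 or F/R/C replicate 3 of day 12 (0.0514 to 0.0553). The comparison called 3338 genes, 1595 higher and 1743 lower, with 1153 without Myf6 replicate 1, 1921 without Myf6 replicate 3 and 1498 without either F/R/C replicate 2 or 3.

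On day 12 Pax7 lay at 7.65 ± 7.47 CPM and Myf5 at 1.55 ± 1.51 CPM with F/R/C, with no counts under Myf6 alone (adjusted p = 0.000585 and 0.00452). F/R/C replicate 3 held 16.22 and 3.29 CPM of them, the others 4.18 and 2.55 CPM of Pax7 and 0.809 and 0.550 CPM of Myf5. Of 20 stem and progenitor genes 8 were higher and 3 lower (9 and 3 adjusted over the list alone). Ckm was higher at 52.63 ± 12.66 against 12.13 ± 3.202 CPM (2.12, adjusted p = 0.00144). Not called were Myog at 739.8 ± 70.8 against 644 ± 202 CPM (adjusted p = 0.792), Myh3 at 5591 ± 806 against 3141 ± 870 CPM (adjusted p = 0.158) and Acta1, the skeletal alpha-actin, at 4956 ± 1237 against 4003 ± 1308 CPM (adjusted p = 0.642). Wnt/beta-catenin response genes were higher in 8 of 13 cases and lower in 2 (10 and 2 adjusted over the list alone; camera adjusted p = 0.000536, adjusted p = 0.16 with an estimated correlation), including Axin2 (2.21, SE 0.35) and Notum (4.38, SE 0.64). All 13 mitochondrially encoded genes were higher (13 adjusted over the list alone), with mt-Nd1 at 3568 ± 555 against 1401 ± 106 CPM. Interferon response genes were lower in 12 of 16 cases (15 adjusted over the list alone), and the chemokine Cxcl12 fell from 535 ± 372 to 26.8 ± 4.68 CPM. Magel2 rose by 7.47 (SE 0.86) and Myoz1 by 5.27 (SE 0.30). The Myf5 call was lost in a fit of the groups compared (0.0645, the highest of its alternatives, whose lowest was 3.44e-07), and Myf6 (-1.49, adjusted p = 0.105) was called without Myf6 replicate 2 (0.0297) or with a replicate block (0.0346). The comparison called 2687 genes, 1314 higher and 1373 lower, but 1579 without Myf6 replicate 1, 1484 without Myf6 replicate 3, 1444 without F/R/C replicate 3 and 452 with only the groups compared in the fit.

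The lentiviral clones, set against MEFs before induction, held the stem cell and the contractile genes together. Pax7 lay at 83.1 ± 27.9 against 0.0127 ± 0.0221 CPM (12.27, SE 1.13) and Myf5 at 24.0 ± 3.99 CPM against no counts, at least 636-fold higher (floor of 3 counts over the group). Myod1 was at 242 ± 51.7, Myh3 at 6146 ± 1233 and Myh8 at 6748 ± 2130 CPM, against 0.0240 ± 0.0209, 0.122 ± 0.149 and 0.0268 ± 0.0233 CPM in MEFs. Of 20 stem and progenitor genes 16 were higher and 1 lower (16 and 2 adjusted over the list alone), and all 60 differentiation and sarcomere genes were higher, the same adjusted over the lists alone. Fibroblast genes were lower in 23 of 29 cases (24 adjusted over the list alone): Thy1 fell from 1090 ± 88.5 to 12.2 ± 9.76 CPM and Col1a1 from 8143 ± 1477 to 32.7 ± 33.7 CPM. Of 14 TGF-beta response genes 12 were lower (12 adjusted over the list alone). Cell cycle genes gave 4 higher and 1 lower of 26 (0 and 0 adjusted over the list alone). Myf6 lay at 67.2 ± 42.95 against 25.9 ± 8.06 CPM (1.38, adjusted p = 0.0616) and was called in 3 of 6 alternatives, whose adjusted p ran from 0.0121 to 0.0705. It was also called without clone replicate 1 (0.0372), Myf6 replicate 1 or 2 of day 12 (0.0416 and 0.0354) or F/R/C replicate 2 of day 12 (0.0486). The comparison called 9908 genes, 5160 higher and 4748 lower.

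The MyoD experiment asked whether Myf6 with F/R/C needs endogenous MyoD. Before induction, on day 0, the knockout MEFs already held more muscle transcripts than wild-type MEFs. All 29 called genes were higher in the knockout (449 genes had an unadjusted p below 0.05). Myog lay at 22.2 ± 9.32 against 1.38 ± 0.968 CPM (4.02, SE 0.62, adjusted p = 0.00441), Mymk at 9.18 ± 5.23 against 0.973 ± 0.663 CPM (adjusted p = 0.0043) and Mymx at 1.53 ± 0.937 against 0.0643 ± 0.0619 CPM (adjusted p = 0.00431). Of 17 differentiation and fusion genes 8 were higher (13 adjusted over the list alone; camera adjusted p = 5.84e-56, adjusted p = 0.000322 with an estimated correlation), of 15 embryonic and slow genes 4 (12 adjusted over the list alone), of 28 fast and mature genes 4 (17 adjusted over the list alone) and of 19 stem and progenitor genes 4 (5 adjusted over the list alone). Among them were the cardiac actin Actc1 (3.43, SE 0.58), Myh1 (4.73, SE 0.78), Chrng (4.35, SE 0.74) and the growth factor receptor Fgfr4 (4.65, SE 0.70). Myod1 was higher in the knockout by 5.09 (SE 0.61). The fibroblast genes Thy1 (997 ± 219.5 against 991 ± 82.6 CPM) and Col1a1 (11030 ± 3210 against 11800 ± 2071 CPM) did not pass (adjusted p = 1 for both). None of 8 macrophage and blood genes was called (0 adjusted over the list alone), but the list was lower as a set (camera adjusted p = 5.46e-14, adjusted p = 0.00183 with an estimated correlation), with Lyz2 at 3.17 ± 1.70 against 8.56 ± 2.88 CPM (adjusted p = 0.927). Zfp14 (chromosome 7, 30036359 to 30051380), chosen after its values were seen, was higher at 7.54 ± 0.469 against 2.07 ± 0.160 CPM (adjusted p = 0.00158). The number of called genes was 45 without knockout replicate 1, 18 without knockout replicate 3, 5 without wild-type replicate 1, 8 without wild-type replicate 3 and 44 without knockout replicate 2 of day 2. Without wild-type replicate 1 or 3 the adjusted p of Myog was 0.0727 or 0.0728, of Mymx 0.0558 or 0.0587, of Myh1 0.0934 or 0.112, of Actc1 0.128 or 0.112 and of Chrng 0.116 or 0.142. That of Fgfr4 was 0.0603 without replicate 1, and that of Actc1 was 0.0544 without knockout replicate 3. A fit of only these groups called 2 genes and DESeq2 called 85. In the former, Myog, Mymk, Mymx, Myh1, Actc1, Chrng and Fgfr4 had adjusted p from 0.122 to 0.263, and Myh1 0.266 with length offsets, while the alternatives for Myog ran from 6.19e-08 to 0.122.

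On day 2 the only called gene was Gpatch1 (chromosome 7, 35276536 to 35318440), a splicing-related gene, lower in the knockout at 7.89 ± 1.13 against 17.2 ± 0.100 CPM (-1.12, SE 0.16, adjusted p = 0.0124), and 745 genes had an unadjusted p below 0.05. Myog lay at 0.858 ± 0.877 against 2.26 ± 1.89 CPM and Myh3 at 21.9 ± 22.3 against 16.1 ± 11.3 CPM (adjusted p = 1 for both), and no member of the muscle lists was called (1 stem and progenitor gene adjusted over the list alone). The call of Gpatch1 was lost without knockout replicate 1 (0.225) or wild-type replicate 1, 2 or 3 (0.0808, 0.0865 and 0.0829), which left 0 genes (482, 488, 493 and 815 at unadjusted p below 0.05). By contrast 4 genes were called without knockout replicate 2 and 2 without knockout replicate 1 of day 0 or wild-type replicate 2 of day 12. Fitting only the day 2 groups called 6 genes, without Gpatch1 (0.0752, the highest of its alternatives, whose lowest was 6.17e-09), and DESeq2 called 39.

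On day 6, with n = 2 per group, Myod1 was lower in the knockout at 17.3 ± 3.64 against 174 ± 6.36 CPM (-3.33, SE 0.56, adjusted p = 0.0365). The receptor gene Bdkrb1 was at 1.64 ± 0.476 against 16.5 ± 10.3 CPM (adjusted p = 0.0185), Adam23 at 10.1 ± 2.17 against 46.0 ± 15.9 CPM (adjusted p = 0.0226), and Zfp14, again named after its values were seen, was higher at 5.45 ± 1.02 against 1.36 ± 0.427 CPM (adjusted p = 0.0185). Not called were Myog at 324 ± 93.5 against 479 ± 42.3 CPM (adjusted p = 0.876) and Myh3 at 6835 ± 3212 against 5434 ± 14.0 CPM (adjusted p = 0.965). Each of the 4 calls depended on single libraries, since 2, 0, 1 and 1 genes were called without knockout replicate 1, knockout replicate 2, wild-type replicate 1 and wild-type replicate 2. In that order the adjusted p of Myod1 was 0.164, 0.479, 0.299 and 0.354, and the fit without knockout replicate 2 had 612 genes at unadjusted p below 0.05. Myod1 was also lost without 10 of the 22 other libraries (up to 0.068), and over its alternatives its adjusted p ran from 2.56e-05 to 0.0783. Bdkrb1 was lost without either knockout library or wild-type replicate 2 (up to 0.479), Adam23 without either knockout library or wild-type replicate 1 (up to 0.558) and Zfp14 without knockout replicate 2 or either wild-type library (up to 0.497). With only these groups in the fit 2 genes were called, and with DESeq2 50. The fit of only these groups lost Bdkrb1, Adam23 and Zfp14 (0.26, 0.218 and 0.284, the highest of their alternatives, whose lowest were 7.02e-08, 2.5e-06 and 2.5e-06), and length offsets lost Adam23 and Zfp14 (0.0897 and 0.0783).

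**Figure D4:**
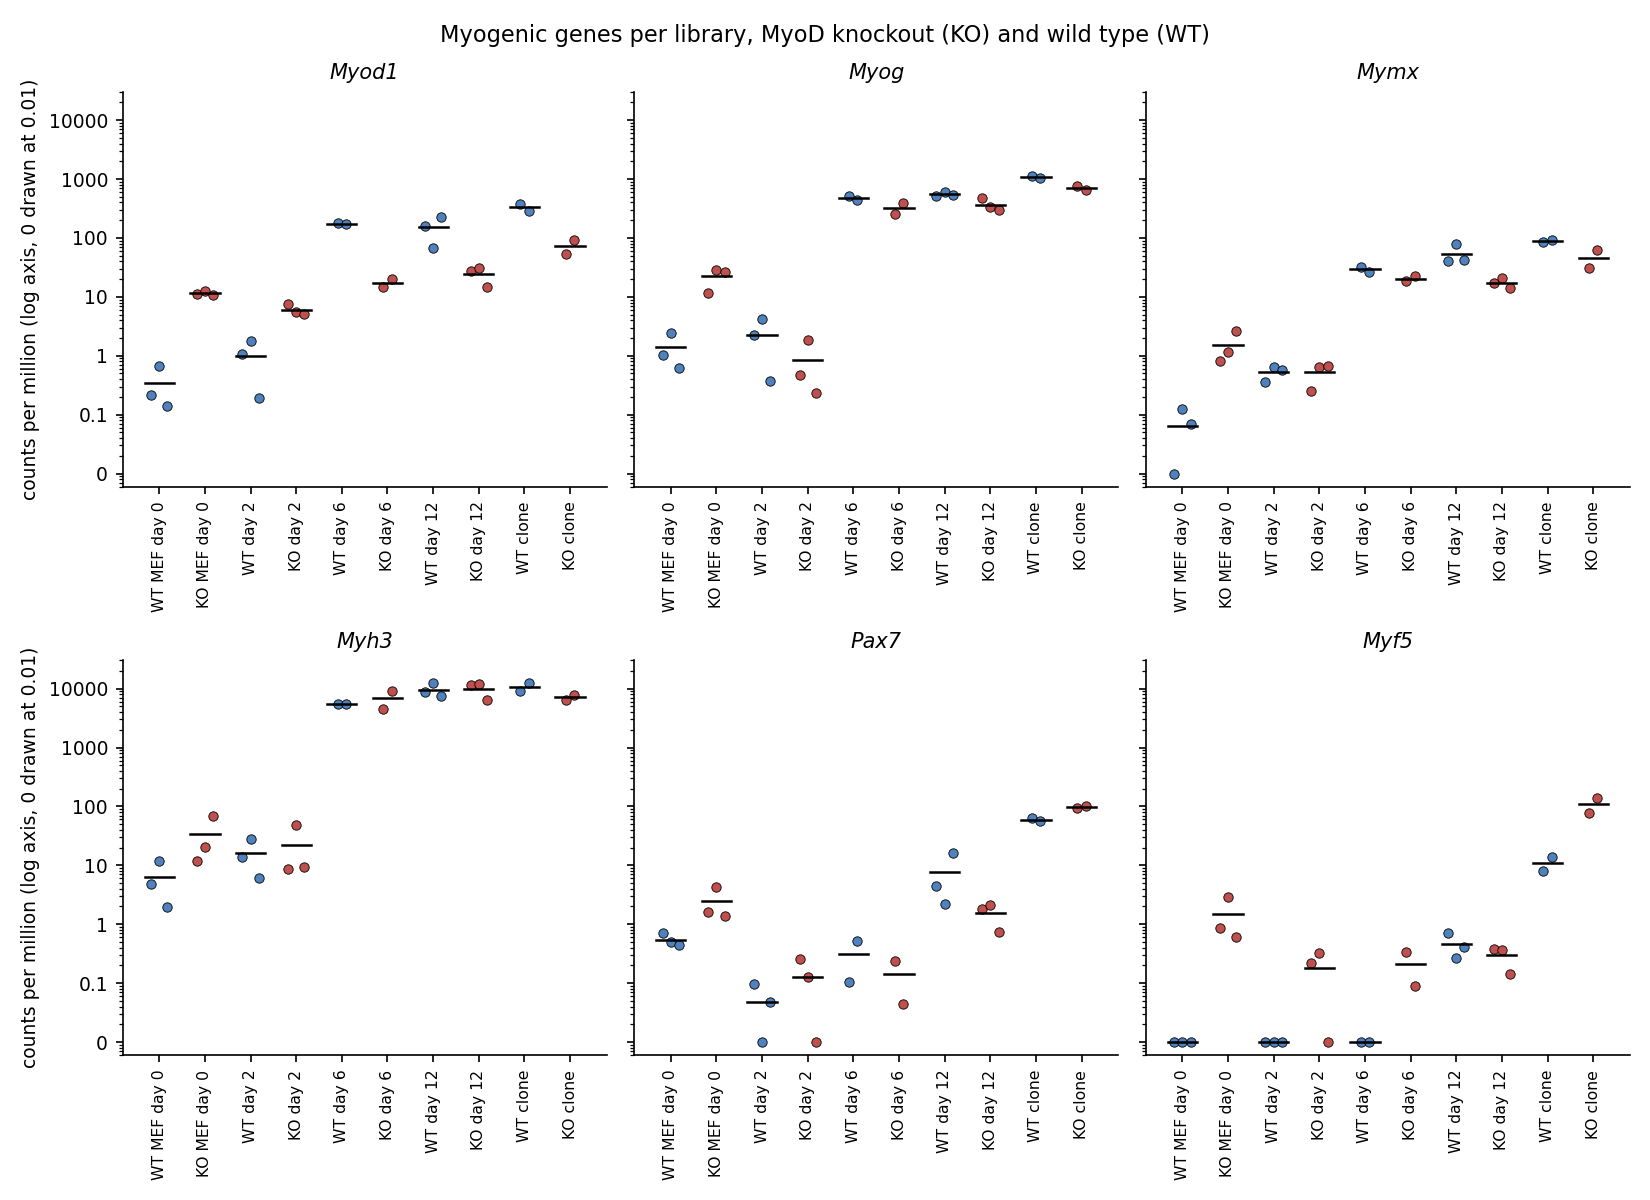
Each point is a library and each line a group mean, in CPM on a log axis, for 6 myogenic genes in the wild-type (WT) and knockout (KO) groups. Myog lay at 22.2 ± 9.32 CPM in knockout and 1.38 ± 0.968 CPM in wild-type MEFs on day 0, and at 368 ± 89.8 and 557 ± 47.0 CPM on day 12.

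On day 12 Myh3 lay at 9950 ± 3056 against 9623 ± 2685 CPM (adjusted p = 0.998), Mymk at 320 ± 91.4 against 354 ± 47.1 CPM (adjusted p = 0.997) and Myog at 368 ± 89.8 against 557 ± 47.0 CPM (adjusted p = 0.953). Of the 60 differentiation and sarcomere genes none was called (2 differentiation and fusion genes lower adjusted over the list alone). The fusion gene Mymx was at 17.2 ± 3.56 against 53.9 ± 21.8 CPM (-1.65, adjusted p = 0.276), and only DESeq2 called it (0.0163, while the other alternatives reached 1). Called lower were Myod1 (-2.65, SE 0.44, adjusted p = 0.027), the somite regulator Dmrt2 (0.430 ± 0.209 against 2.90 ± 1.10 CPM, adjusted p = 0.027), the retrotransposon-derived Rtl3 (5.17 ± 0.914 against 16.8 ± 1.50 CPM, adjusted p = 0.027) and, chosen after its values were seen, Col6a6 (chromosome 9, 105687809 to 105828160; 1.23 ± 0.726 against 7.89 ± 0.476 CPM, adjusted p = 0.027). Zfp14 (7.17 ± 3.03 against 2.07 ± 0.0431 CPM, adjusted p = 0.00885) and Klk1b22 (chromosome 7, 44112673 to 44116922; 1.10 ± 0.381 CPM against 0, adjusted p = 0.04), likewise chosen afterwards, were higher. Myod1, the targeted gene itself, and Dmrt2 were the 2 called members of 19 stem and progenitor genes (3 adjusted over the list alone). These 6 calls depended on single libraries. Without knockout replicates 1, 2 and 3 the counts were 1, 2 and 3, without wild-type replicates 1, 2 and 3 they were 3, 3 and 0 (1294 genes at unadjusted p below 0.05 in the last), and without either wild-type clone 10 genes were called. Myod1 was lost without each of the 6 libraries except wild-type replicate 2, with adjusted p up to 0.17, and without knockout replicate 3 of day 0 (0.05). Dmrt2 was lost without 5 of the 6 (up to 0.176), Rtl3 and Klk1b22 without all 6 (up to 0.191 and 0.176), Col6a6 without 5 (up to 0.17) and Zfp14 without wild-type replicate 3 (0.0862). Klk1b22 was also lost without 8 of the 20 other libraries (up to 0.0873). Fitting only these groups with edgeR called 0 genes (401 at unadjusted p below 0.05), with an adjusted p of 1 for Myod1, whose alternatives went down to 8.09e-05, and DESeq2 called 35.

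The clones compared the genotypes in the established state with n = 2 per group, so that a clone and a genotype can hardly be told apart. Myf5 was higher in knockout clones at 108 ± 41.3 against 10.9 ± 3.91 CPM (3.31, SE 0.71, adjusted p = 0.0246), and Myod1 was lower at 72.2 ± 26.3 against 331 ± 61.6 CPM (-2.20, SE 0.53, adjusted p = 0.028). Pax7 lay at 99.1 ± 5.88 against 59.5 ± 5.45 CPM (adjusted p = 0.601), Myog at 699.8 ± 86.4 against 1087 ± 82.1 CPM (adjusted p = 0.61) and Myh3 at 7091 ± 824 against 10800 ± 2606 CPM (adjusted p = 0.747). The hindlimb regulator Pitx1 was at 15.9 ± 8.75 against 0.0241 ± 0.0341 CPM and Hoxa10 at 28.6 ± 1.21 against 0.241 ± 0.341 CPM, higher in knockout clones, while Hoxc10, chosen after its values were seen, did not pass (1.11, adjusted p = 0.486). Col1a1 was lower at 6.86 ± 4.39 against 58.9 ± 70.2 CPM (-3.10, adjusted p = 0.0358), as was Lef1, a Wnt/beta-catenin response gene, at 2.55 ± 0.741 against 20.2 ± 12.6 CPM. The slow myosin Myh7 was also called lower (-1.90, adjusted p = 0.0472), a call lost without any of the 4 clones (0.0757 to 0.142) and without 16 of the 22 other libraries (up to 0.0642). Of 14 Wnt/beta-catenin response genes 1 was lower, of 29 fibroblast genes 2 and of 8 smooth muscle genes 1 (1, 2 and 4 adjusted over the lists alone). The comparison called 589 genes, 319 higher and 270 lower, but 884 without knockout clone 1, 385 without knockout clone 2, 183 without wild-type clone 1, 2419 without wild-type clone 2 and 970 without wild-type replicate 2 of day 12. Without knockout clone 2 or wild-type clone 1 the adjusted p of Myf5 was 0.0927 or 0.187 and that of Lef1 0.107 or 0.198. Myod1 reached 0.106, 0.0537 and 0.146 without knockout clones 1 and 2 and wild-type clone 1, and Col1a1 0.136, 0.0637 and 0.746 without knockout clones 1 and 2 and wild-type clone 2. With only the clones in the edgeR fit 0 genes were called (673 at unadjusted p below 0.05), with an adjusted p of 0.921 for each gene named here except Hoxc10 (0.939), while the alternatives for Pitx1 went down to 1.3e-07 and those for Myh7 to 0.023, and DESeq2 called 1391. Lef1 and Myh7 were also lost with length offsets (0.14 for both) and Myh7 without a filter (0.0531).

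Within each genotype, day 12 was set against day 0 to show the course of induction. Wild-type cultures raised Myog from 1.38 ± 0.968 to 557 ± 47.0 CPM (8.67, SE 0.72), Mymk by 8.54 (SE 0.56), Myh3 by 10.60 (SE 1.05) and Myh4 by 14.33 (SE 1.13). Knockout cultures raised Myog from 22.2 ± 9.32 to 368 ± 89.8 CPM (4.05, SE 0.57), Mymk by 5.12 (SE 0.46), Myh3 by 8.19 (SE 0.95) and Myh4 by 10.28 (SE 0.87). All 28 fast and mature and all 15 embryonic and slow genes were higher in both genotypes, as were 17 of 17 differentiation and fusion genes in wild type and 16 of 17 in the knockout (the same adjusted over the lists alone). The cAMP target Sik1 rose by 4.23 (SE 0.27) in wild type and 3.77 (SE 0.26) in the knockout, and mt-Nd2 by 3.82 and 3.94 (SE 0.24 each), with all 13 mitochondrially encoded genes higher in both (13 adjusted over the list alone). All 26 cell cycle genes were lower in both (26 adjusted over the list alone), with Mki67 at 32.9 ± 20.3 against 252 ± 8.19 CPM in wild type and 25.5 ± 14.3 against 211 ± 18.3 CPM in the knockout. Interferon genes were lower in 14 of 16 cases in each genotype (14 adjusted over the list alone), with Isg15 down by 5.00 on the log2 scale in wild type and Oasl2 down by 5.23 in the knockout. Col1a1 fell from 11800 ± 2071 to 724 ± 443 CPM in wild type and from 11030 ± 3210 to 433 ± 201 CPM in the knockout. Thy1 fell by 2.48 on the log2 scale in the knockout and by 1.59 in wild type (adjusted p = 0.0138), where the call was lost without replicate 2 or 3 of day 12 (0.0513 and 0.0618). Myod1 rose by 8.82 (SE 0.64) in wild type and by 1.07 (SE 0.43, adjusted p = 0.0375) in the knockout. The latter call was lost without replicate 1, 2 or 3 of day 0 (0.086, 0.0629 and 0.0955), without replicate 1 or 2 of day 12 (0.0939 and 0.13) and with a block for replicate number within genotype (0.0591, the highest of its alternatives, whose lowest was 0.0141). Wild type called 9759 genes, 5153 higher and 4606 lower. The knockout called 9786, 5004 higher and 4782 lower.

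The difference between these courses was tested by the interaction of genotype and day. From day 0 to day 12, 11 genes differed, all with the lower log2 change in the knockout. Besides Myod1 (difference of log2 changes -7.75, SE 0.75, adjusted p = 4.64e-05) these were the myoblast cadherin Cdh15 (-4.00, SE 0.47), the fusion genes Mymx (-6.08, SE 0.76) and Mymk (-3.42, SE 0.62), Myog (-4.62, SE 0.79), Fgfr4 (-5.16, SE 0.85), the receptor kinase Musk (-5.03, SE 0.93), the sarcomere-associated Trim55 (-4.70, SE 0.75) and, chosen after their values were seen, Arpp21 (-4.25), Rapsn (-4.12) and Pitx3 (-4.17). Their levels on day 12 were closer than these differences: Cdh15 lay at 568 ± 87.3 in knockout and 640.2 ± 79.9 CPM in wild-type cultures, Musk at 77.6 ± 21.1 and 80.3 ± 3.27 CPM and Arpp21 at 97.1 ± 18.3 and 137 ± 14.4 CPM. On day 0 Arpp21 lay at 4.83 ± 2.56 in knockout and 0.350 ± 0.162 CPM in wild-type MEFs, Rapsn at 1.56 ± 0.952 and 0.120 ± 0.111 CPM and Pitx3 at 0.952 ± 0.723 and 0.109 ± 0.0877 CPM. Of 17 differentiation and fusion genes 5 differed (13 adjusted over the list alone; camera adjusted p = 5.4e-33, adjusted p = 0.00545 with an estimated correlation) and of 19 stem and progenitor genes 3 (7 adjusted over the list alone). From day 0 to day 2 the only called gene was Cdh15 (-3.67, SE 0.46, adjusted p = 0.00317), and Myog (-5.40, SE 0.89) had an adjusted p of 0.0593. Myog passed without knockout replicate 1 (0.013) or wild-type replicate 2 of day 0 (0.0254), knockout replicate 2 (0.00907) or wild-type replicate 3 of day 2 (0.00421) or knockout replicate 3 of day 12 (0.045), and over its alternatives ran from 3.2e-06 to 0.163. At unadjusted p below 0.05 there were 579 genes for day 12 and 500 for day 2. The day 12 count ran from 3, without wild-type replicate 1 or 3 of day 0, to 21, without knockout replicate 1 of day 0. The day 2 count ran from 1 to 13, the latter without knockout replicate 2 of day 2. Without wild-type replicate 1 or 3 of day 0 the adjusted p of Arpp21 was 0.0797 or 0.0713, of Trim55 0.098 or 0.0943 and of Rapsn 0.098 or 0.107. Fgfr4 lost its call without any wild-type library of day 0, wild-type replicate 3 of day 12 or knockout replicate 2 of either day (0.0513 to 0.113). Pitx3 and Myog lost theirs without wild-type replicate 1 or 3 or knockout replicate 2 of day 0, wild-type replicate 3 or any knockout library of day 12 (up to 0.129 and 0.147), and Myog also without knockout replicate 3 of day 0 (0.0814). Mymk and Musk lost theirs without each of the 12 libraries compared except knockout replicate 1 of day 0 (up to 0.163 and 0.27), and Cdh15, Mymx and Myod1 without none of the 12. Mymk and Musk also lost it without 10 and 11 of the 14 other libraries (up to 0.0671 and 0.0729). A fit of only the groups compared called 1 gene for day 12, Myod1, and 12 for day 2, while DESeq2 called 40 and 38. The former fit ended the other 10 calls of day 12 (0.0511 for Cdh15, whose alternatives went down to 1.72e-14, and 0.362 for Mymk, down to 0.000133). Musk was also lost with RLE size factors (0.0539), a replicate block (0.0506) and a block within genotype (0.129), and Pitx3 with length offsets (0.0766).

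**Figure D5:**
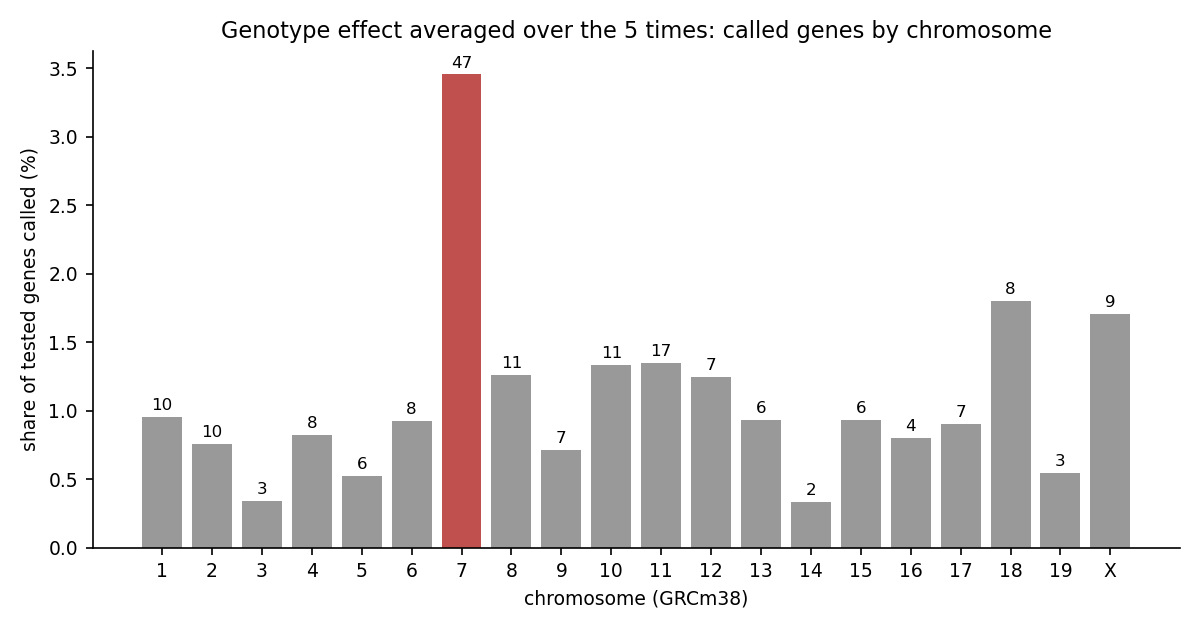
The bars give the percentage of tested genes called for the genotype effect averaged over the 5 times of the MyoD experiment, by chromosome, with the number called above each bar. Chromosome 7, which holds Myod1, had 47 called genes of 1361 tested.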

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

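Chosen only after the result was seen were the tests of carry-over and of fewer fibroblasts for the macrophage genes, of carry-over and of the loss of MyoD for the muscle genes of knockout MEFs, both tests on chromosome 7, the fits of days 0, 2 and 12 alone and the split by Ddx3y. The other tests in this part were set before their results were seen.

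The interaction of MyoD genotype and day called 1 gene from day 0 to day 2, Cdh15. From day 0 to day 12 it called 11, all with the lower change in the knockout. Higher knockout levels on day 0 are part of this, as in Myog, Mymk, Mymx, Fgfr4 and Arpp21. In a fit of only the groups compared the real grouping gave 12 genes for day 2 and 1 for day 12, the targeted Myod1. Of 100 random regroupings by genotype within each day, the real one included, 8 gave as many genes for day 2 (highest other 384). For day 12 it was 21 (highest other 995), so chance cannot be excluded for either count. Regroupings with many more genes point to a structure that genotype does not follow. For the genotypes on single days 10 splits are too few for a share under 0.05. There 4 of 10 splits gave at least the real 2 genes on day 0 (highest other 5) and 2 of 10 the real 6 on day 2 (highest other 179). On day 12 the real count was 0, which each of the 10 reaches, so their number says nothing (highest other 617; edgeR, with 401 genes at unadjusted p below 0.05, and 35 called with DESeq2).

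The 179 genes of day 2 set knockout replicates 1 and 3 and wild-type replicate 3 against the rest, and the 617 of day 12 knockout replicates 1 and 2 and wild-type replicate 2 against the rest. Neither follows the Y-linked gene Ddx3y. It exceeded 10 CPM under 1 of 3 replicate numbers in knockout and 2 of 3 in wild type, clones aside, and under none in both, so the sex of the MEF lines is unevenly spread over the genotypes. The split by Ddx3y gave 5, 4 and 5 genes on days 0, 2 and 12. What part sex has in the genotype comparisons stays open.

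Splits of the libraries of the other comparisons with 3 libraries per group were likewise too few, at 10 each, with 1 split, the real one, giving as many genes. In the order of the report the TetO comparisons gave 7834, 9195, 9525, 7596, 2851, 9186, 9177, 3968 and 9394 genes. The lentiviral ones gave 8267, 5570, 4533, 452 and 9108, and the courses of wild type and knockout 8840 and 8818. The highest other split gave 0 genes in each (edgeR). Where numbers pair the libraries, the real split parts all 3 pairs, as 3 of the other splits do, and the remaining 6 part 1.

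Cultures with TetO Myf6 alone held macrophage transcripts on day 12. The 12 genes of the fixed list summed to 682 to 1610 CPM in these 3 libraries, although the cells were Thy1-selected per the labels. Of the list 4 genes exceeded 1 CPM in TetO MEFs and 0 belong to another list. Reads carried over from another library are argued against, since the lowest of the 3 sums was 9.87 times the highest of the other 74 libraries. A lower share of fibroblasts, which would raise other cell types alike, stays open. The adipocyte median fell by 5.56 on the log2 scale (-5.56), but adipocyte genes rose in medium itself, so this cannot tell. This list was chosen after the macrophage median came only 0.98 above the epithelial one. Macrophages remain a candidate explanation: 10 of 10 macrophage genes outside the list were called higher than in medium. Expression by other cells was not tested.

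Knockout MEFs of day 0 held more muscle transcripts than wild-type MEFs, with 59 of 60 genes of the 3 differentiation and sarcomere lists at a higher mean, called or not, and sums of 940 to 1700 against 704 to 783 CPM. Reads carried over from induced libraries are argued against: the 3 knockout libraries held 1 count of Myf6, where carry-over of the muscle reads needs 331 at the fewest, a share of 0.003. Muscle-lineage cells among these MEFs may be a source, as 8 of 10 muscle genes outside the lists had a higher mean in the knockout, the fewest that the prediction allowed and none of them called (Hrc 2.66 ± 1.4 against 0.358 ± 0.0505 CPM, adjusted p = 0.0785; Srl 11.5 ± 4.89 against 4.85 ± 1.13 CPM). The labels call these cells MEFs, without the Thy1 selection of the other experiments, and 6 of 17, 12 of 15 and 12 of 28 genes of these lists exceeded 1 CPM in wild-type MEFs, with 0 in another list. Loss of MyoD raising these genes cannot be told apart from the MEF line, which differs with genotype: the median difference was 2.6 on day 0, then 0.01, 0.08, 0.04 (day 12) and -0.13 in the clones.

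Genotype differences gathered on chromosome 7, which holds Myod1. The genotype effect averaged over the 5 times called 190 genes, 47 of them on this chromosome, or 24.7 percent against 8.11 percent of the tested genes (Fisher exact one-sided p 2.6e-12), and 41 of the 47 within 50 Mb of Myod1, a window with 832 of the 1361 genes tested there. A segment of another strain linked to the Myod1 allele is a candidate explanation that these 47 genes go with. Absence of MyoD acting on them cannot be told apart from it: of 42 genes called from the later times alone 85.7 percent (36) had the same sign on day 0, between the bounds set for either answer, against 126 of 189 on other chromosomes. These calls take the times of a MEF line as independent. With only days 0, 2 and 12 edgeR called 37 genes, 18 of them on chromosome 7, and with these libraries summed by replicate number, 3 sums per genotype, 0. Of 971 genes at unadjusted p below 0.05 in the sums, 132, or 13.6 percent, lay on chromosome 7, against 8.21 percent of the tested genes (Fisher exact one-sided p 3.55e-09). The 37 go with fewer times and libraries and the 0 with summing and fewer units, while the share on chromosome 7 is raised in all 3 fits. No variant was looked at here.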

How the results depend on the processing

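Chosen after the data were seen were the fit without both F/R/C libraries numbered 1 of days 6 and 12 (4 TetO comparisons), the block for replicate number within MyoD genotype (4 comparisons) and 2 fits of the averaged MyoD genotype effect, with 190 genes over 5 times, 37 over days 0, 2 and 12 alone and 0 with these summed by replicate number (edgeR, 971 at unadjusted p below 0.05). All other alternatives were planned, and none failed to run. Of 282 values for single genes, 220 stayed on their side of the threshold with their direction in each fit made, and 62 changed in at least 1. With RLE size factors 2 calls were lost, without a filter 2 lost and 1 gained, with a replicate block 4 and 5, with length offsets 10 and 1, with DESeq2 3 and 5, with the block within genotype 2 of 40 lost, and in fits of only the groups compared (278 values) 38 lost and 4 gained. Leaving out single libraries lost 220 calls and gained 16 in 7793 values. The 1 reversal was Pax7 in TetO F/R/C against Myf6 on day 12, at 0.24 with all libraries, -2.74 without both F/R/C libraries numbered 1, and from -2.76 to 0.78 without single libraries (F/R/C replicates 1 and 2 of day 12). The cause was not tested, beyond the fewer libraries. The fit without both libraries also gained 3 calls in 61 values.

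Counts of called genes stayed within 1.5 times in all 23 comparisons with RLE size factors, in the 4 with a block within genotype, and in 22, 21, 20, 16 and 12 without a filter, with length offsets, with a replicate block, with DESeq2 and in fits of only the groups compared. The last gave 7834 and 7596 genes for TetO day 2 (Myf6 against medium, F/R/C against Myf6), 2851 for F/R/C on day 6 and 452 for lentiviral F/R/C on day 12. For knockout against wild type it gave 2, 6, 2 and 0 on days 0, 2, 6 and 12 and 0 for the clones (edgeR, 401 and 673 at unadjusted p below 0.05 for the last 2), and for the interactions 12 (day 2) and 1 (day 12). DESeq2 gave 85, 39, 50, 35 and 1391 for the genotypes in that order and 38 and 40 for the interactions. A replicate block gave 2 genes on day 2 for the genotypes and 10 and 18 for the interactions. Its numbers join unrelated MEF lines of the 2 genotypes. Without a filter the day 2 interaction had 3 genes, and with length offsets 4, while the genotypes on day 6 had 1. Without both F/R/C libraries numbered 1 the F/R/C effect on day 2 had 6417 genes and clones against F/R/C 6603. The cause was not tested. Fits of only the groups compared have fewer samples. On TetO day 2 they lack F/R/C replicate 1 of day 6 (7038 and 6231 genes without it alone).

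Leaving out each library in turn (621 counts) moved 51 beyond 1.5 times. The ranges were 2988 to 6731 for TetO clones against F/R/C, 1153 to 3989 and 1444 to 3640 for lentiviral F/R/C on days 2 and 12, and, for the genotypes, 5 to 45, 0 to 4, 0 to 6, 0 to 10 and 183 to 2419. For the interactions they were 1 to 13 and 3 to 21. The values at 0 had 482 (without knockout replicate 1 of day 2), 488, 493 and 815 (without wild-type replicates 1, 2 and 3 of day 2), 612 (without knockout replicate 2 of day 6) and 1294 genes (without wild-type replicate 3 of day 12) at unadjusted p below 0.05. In all 9 TetO comparisons the highest count came without F/R/C replicate 1 of day 6. Genes called both with all libraries and in all fits without 1 numbered 3432, 6745 and 7097 of 5017, 8522 and 9035 for Myf6 against medium, 2637, 5138 and 5795 of 4208, 7394 and 7824 for F/R/C, and 5, 0, 0, 0 and 65 of 29, 1, 4, 6 and 589 for the genotypes.

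Counts of called list members moved in 31 of 483 cases with DESeq2, 5 with RLE, 21 without a filter, 91 with only the groups compared, 20 with a block and 34 with length offsets, and in 16 of 84 without the libraries numbered 1. Of 483 list tests 170 passed with the preset correlation and 31 of these with an estimated one, while a block added 3. Medians of all genes moved by at most 0.11 on the log2 scale under RLE and DESeq2 scaling, and by 0.16 in TetO F/R/C on day 6 without the libraries numbered 1. In simulated data with few changed genes, 30 to 68 percent of 2-fold changes were called, and recall with many changed genes was not tested.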

Other observations

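No tests were chosen for this part. The genes of its first paragraph were chosen after their values were seen, while Thy1 and Col1a1 belong to the panel. In the MyoD experiment MEFs of both genotypes held Pitx1 (10.2 to 17.3 CPM in knockout and 8.84 to 10.5 CPM in wild type) and Hoxa10 (30.9 to 42 and 27.2 to 37.9 CPM). Knockout clones held Pitx1 (9.68 to 22 CPM) and Hoxa10 (27.8 to 29.5 CPM), while wild-type clones held 0 to 0.0482 CPM of Pitx1 and 0 to 0.482 CPM of Hoxa10. Hoxc10 was low in clones of both genotypes (0.325 to 3.15 and 0.397 to 1.16 CPM), and TetO clones were alike in Pitx1 (1.31 to 1.78 CPM) and Hoxa10 (5.53 to 6.25 CPM). Alx1 ranged from 0.0964 to 24.6 CPM over the 2 wild-type clones and from 2.38 to 108 CPM over the 3 lentiviral clones, against 0.728 to 0.96 CPM in wild-type MEFs and 2.09 to 2.57 CPM in lentiviral MEFs.

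Thy1 lay at 351 to 516 CPM and Col1a1 at 2090 to 2720 CPM in TetO clones. Lentiviral clones held 6.36 to 23.4 CPM of Thy1 and 5.53 to 70.4 CPM of Col1a1, and the clones of the MyoD experiment 2.16 to 12.5 and 3.75 to 109 CPM. The experiments differ in strain, in how Myf6 was delivered and, for the lentiviral one, in library preparation, and the differences were not tested.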
